A study of Mus musculus with 22 samples.

How the data were processed

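Polyadenylated RNA of mouse small-intestinal crypts released with EDTA and of dissected small-intestinal adenomas was profiled by RNA-seq in 18 libraries, and binding of the cohesin subunit Rad21 was profiled by ChIP-seq in WT crypts and Apc Min adenomas. Per the labels, RNA libraries were made with TruSeq chemistry and sequenced as 50 bp paired-end reads, and chromatin was precipitated with the Rad21 antibody ab992. The processing notes of the labels list Bowtie 0.12.8, TopHat 1.4.1, HTSeq 1.0.0, BWA and limma with the mouse build mm9, without giving the role of each.

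The authors' expression files hold values per RefSeq transcript accession. Deposited raw counts cover 5 of the 6 RNA groups in 3 tables of 19938, 18520 and 18207 transcripts, each without transcripts at 0 in all of its 6 libraries. The Apc Min crypt libraries stand in 2 of these tables, with equal counts for the 20145 transcripts in either table when a transcript absent from 1 table is taken as 0. Apc Min adenomas are held only in a deposited matrix of log2 normalized CPM, which covers 12858 transcripts of the WT crypt, Apc Min crypt and Apc Min adenoma libraries. Its values equal log2 of the count plus 0.5 over an effective library size in M. Inverting this formula gave whole numbers, within 0.001, for 100% of the values, and these equalled the deposited counts for 12858 of 12858 transcripts in each WT and Apc Min crypt library. Counts of the Apc Min adenomas were recovered in the same way, so 7539 of the 20397 transcripts of the joined tables have no value in that group. The authors' peak files list MACS peaks with a score per peak, taken here as -10 log10 of the peak p-value from the MACS convention; the files do not state the scale. All columns of sample values were used; the input libraries have no table of their own.

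Transcripts were matched to symbols by accession: 19977 of 20397 had a symbol, giving 18299 symbols, of which 1447 had more than 1 accession. Reads shared by near-identical copies may not be counted, so the absolute level of such transcripts is a minimum. Samples were grouped by tissue and genotype label, with 3 libraries in each RNA group. The groups and tests, 29 gene lists (680 of 709 entries matched to a measured accession, the most abundant per symbol) and the rule for named genes were fixed before the data were examined. The lists cover absorptive enterocyte, goblet, Paneth, tuft, enteroendocrine and crypt stem cell genes, Wnt/beta-catenin targets, cell cycle, ribosome biogenesis, double-strand break repair, p53 targets, cohesin factors, clustered protocadherins, Hox and imprinted genes. The others cover interferon-stimulated, MHC class II, antimicrobial, fetal-like and extracellular matrix genes, and markers of T/NK, B and plasma, macrophage to mast cell, fibroblast, smooth muscle, endothelial, erythroid, exocrine pancreas and enteric neuron cells.

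The groups were compared in 7 pairs, and 2 interaction contrasts over 4 groups each tested whether the effect of the Rad21+/- label differed with the Apc genotype of crypts or between crypts and adenomas. Comparisons without Apc Min adenomas used the edgeR 4.0.16 quasi-likelihood F test on deposited counts, with filterByExpr (minimum count 10, minimum total 15), TMM normalization and only the libraries compared. Apc Min adenomas were compared with Apc Min and WT crypts by the limma 3.58.1 moderated test with a mean-variance trend on the deposited log2 values. For the comparison of the 2 adenoma groups and the tissue interaction, log2 values with a prior count of 0.5 were rebuilt from deposited and recovered counts with 1 joint TMM normalization over the 12858 transcripts, and tested with limma. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Lists with at least 5 tested genes were tested with camera, two-sided, at a preset inter-gene correlation of 0.01, with the correlation estimated as an alternative; fry was a further alternative, which tests whether the genes of a list move on balance one way and does not compare them with other genes. Levels printed beside a fold change are normalized CPM from the fit of that comparison, and levels compared over all 6 groups come from 1 joint TMM normalization. A group with 0 counts over its 3 libraries was set to 3 counts for a lower bound of the fold, and 1 to 3 counts give a ratio of totals with a 95% counting interval. Intervals and floors cover counting error only.

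Rad21 and Apc are named in every comparison. Then come the 10 largest rises and 10 largest falls (5 and 5 against WT crypts for adenomas, for Apc Min Rad21+/- adenomas against crypts and for interactions) among genes past the threshold with a mean log2 CPM of at least 1, groups without overlap and an approved-style symbol. Up to 4 members with the smallest adjusted p of each list past its threshold follow, and members of the cohesin, Wnt and stem cell lists may be named anywhere.

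Peaks were compared with bedtools 2.31.1, counting an overlap of at least 1 bp, with exact (Clopper-Pearson) 95% binomial intervals from scipy 1.17.1. The overlap was also counted after moving the crypt peaks 100 times by a random distance along each chromosome. Each ChIP condition has 1 library, so no test between conditions was made. Peaks were not related to changed genes, for want of an annotation on mm9.

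Alternatives were DESeq2 1.42.0, DESeq2 size factors, no filter on low counts, all groups in 1 fit, the replicate number as a block, limma on the deposited log2 values and each library left out in turn. Total counts as the scale, edgeR on recovered counts, a term for libraries with Y-linked transcripts above 10 CPM, deeper libraries thinned at random to the mean total of their partner group, a common peak score of 40 and a peak width limit of 5 kb were chosen after seeing the data. Each test was also run on simulated data, in which counts of 100 transcripts per fold were changed 2-fold or 4-fold. The edgeR or limma test recovered between 6% and 79% of the 2-fold and between 54% and 96% of the 4-fold changes, depending on the comparison. Some calls were of unchanged transcripts: 9 of 122 by edgeR and 43 of 199 by DESeq2 for Rad21+/- against WT crypts. For Apc Min against WT crypts they were 20 of 190 by edgeR and 36 of 224 by DESeq2. For the adenoma groups they were 6 of 87 by limma and 50 of 195 by DESeq2. DESeq2 counts given below may therefore hold more false calls than the threshold implies. Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9.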

Results

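RNA-seq of mouse small intestine covered 6 groups of 3 libraries: crypts labelled wild type (WT), Rad21+/-, Apc Min and Apc Min Rad21+/-, and adenomas labelled Apc Min and Apc Min Rad21+/-. Rad21 encodes a core subunit of cohesin, the ring complex that holds sister chromatids together and shapes chromatin loops. Apc Min is a truncating allele of Apc, a repressor of Wnt signalling, and mice that carry it develop intestinal adenomas. Total counts per library ran from 23.2 to 27.8 M in WT crypts, 35.0 to 50.8 M in Rad21+/- crypts, 22.6 to 27.2 M in Apc Min crypts and 37.5 to 42.8 M in Apc Min Rad21+/- crypts. Apc Min adenomas had 21.6 to 23.7 M recovered counts and Apc Min Rad21+/- adenomas 42.2 to 46.6 M. The libraries with the Rad21+/- label were therefore deeper than their partners in all 3 pairs of groups, and the labels give no batch. Replicates are not stated to be separate animals, so p-values measure the spread between these samples. Unless stated otherwise, levels are mean CPM ± SD and log2 fold changes carry ± SE, with n = 3 libraries per group.

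The first principal component of the 18 libraries held 77.5% of the variance and separated adenomas (scores 70.0 to 104.2) from crypts (-59.8 to -10). The second held 6.8%, with Apc Min Rad21+/- adenoma replicate 1 apart from all others at -48.7. Rad21+/- crypts spread from -38.4 to -10 on the first component. Y-linked transcripts exceeded 10 CPM in 1 of 3 WT crypt libraries, 0 of 3 Rad21+/- crypt libraries, 1 of 3 Apc Min adenoma libraries and all 3 libraries of each other group. Apc Min adenoma replicate 3, with Y-linked transcripts, also held Xist, the RNA of the inactive X chromosome, at 86.0 CPM. The other libraries with Y-linked transcripts had 1.45 CPM or less.

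**Figure D1:**
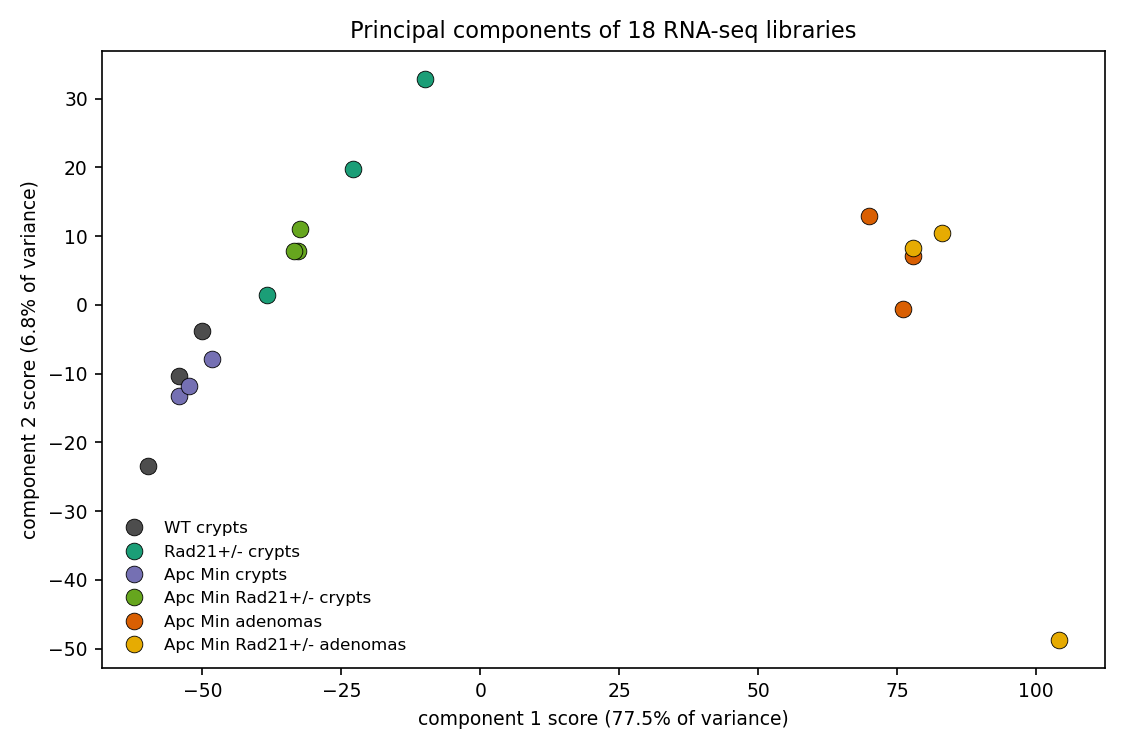
Scores of the 18 RNA-seq libraries on the first and second principal components of log2 normalized counts (arbitrary units), one point per library, coloured by group. Adenomas lie at 70.0 or above on the first component and crypts at -10 or below; 1 Apc Min Rad21+/- adenoma library lies at -48.7 on the second.

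The mean level of Rad21 RNA was not lower in any group labelled Rad21+/- than in its partner group. On 1 joint scale its level was 292.5 ± 37.1 CPM in WT crypts and 344.2 ± 23.9 in Rad21+/- crypts. It was 269.3 ± 7.4 in Apc Min crypts and 341.1 ± 11.8 in Apc Min Rad21+/- crypts, then 256.9 ± 2.15 in Apc Min adenomas and 260.6 ± 33.6 in Apc Min Rad21+/- adenomas. Apc stood at 225.1 ± 11.7, 179.3 ± 32.7, 245.0 ± 11.5, 181.5 ± 16.1, 182.2 ± 23.0 and 200 ± 32.1 CPM in the same order of groups. Counts per transcript do not separate alleles, so the state of the targeted Rad21 allele is not visible in them.

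**Figure D2:**
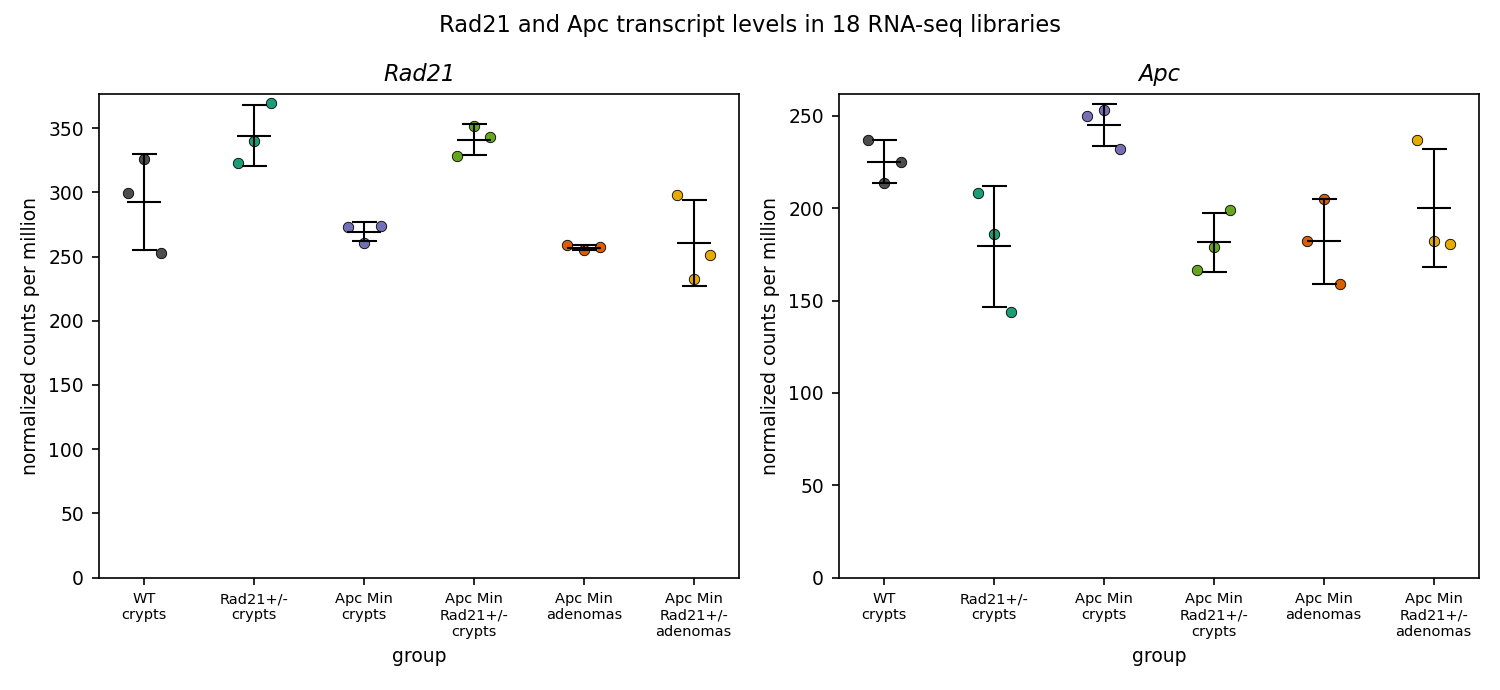
Rad21 and Apc in normalized CPM in each of the 18 RNA-seq libraries (points), with the mean and SD of each group of 3 (bars). Mean Rad21 was 344.2 in Rad21+/- crypts against 292.5 in WT crypts, and 341.1 in Apc Min Rad21+/- crypts against 269.3 in Apc Min crypts.

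Crypts labelled Rad21+/- were compared with WT crypts to ask how crypt expression differs with the Rad21 label. Enterocyte genes lay lower and proliferation, Wnt target and stem cell genes lay higher on balance, although no single gene passed the test. Of 39 absorptive enterocyte genes, 11 were lower when adjusted over the list alone, with a median log2 fold change of -1.14 (camera adjusted p = 4.59e-15; adjusted p = 0.452 with an estimated correlation). Fabp1, which binds fatty acids in enterocytes, was at 1680 ± 417 CPM against 4580 ± 828 (log2 -1.45 ± 0.30, adjusted p = 0.103). The drug-metabolizing Cyp3a11 was at 398 ± 268 against 3140 ± 886 CPM, and Mttp, needed to load fat into lipoproteins, at 64.0 ± 23.6 against 148 ± 19.6. Of 31 cell cycle genes, 17 were higher when adjusted over the list alone, with a median of 0.73 (camera adjusted p = 1.22e-10; adjusted p = 0.463 with an estimated correlation). The mitotic kinase Plk1 was at 56.1 ± 12.8 against 28 ± 5.17 CPM and the ubiquitin conjugase Ube2c at 70.8 ± 14.1 against 33.7 ± 8.78. Wnt targets went both ways over a median of 0.73 for 20 genes, 10 higher and 1 lower over the list alone (camera adjusted p = 4.52e-06; adjusted p = 0.452 with an estimated correlation). Axin2, a feedback inhibitor of the pathway, was at 115 ± 9.1 against 69.2 ± 14.1 CPM and Sox9, a progenitor transcription factor, at 30.7 ± 6.54 against 13.9 ± 3.58, while the factor Sp5 was at 15 ± 4.17 against 27.9 ± 7.98. Lgr5, the receptor that marks crypt base stem cells, was at 21 ± 6.37 against 10.2 ± 6.11 CPM. The list of 17 stem cell genes had a median of 0.68 and none past its own adjustment (camera adjusted p = 1.54e-05; adjusted p = 0.463 with an estimated correlation).

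Interferon-stimulated genes lay lower in the Rad21+/- crypts, with a median of -0.57 over 33 genes and 10 lower when adjusted over the list alone (camera adjusted p = 1.92e-06; adjusted p = 0.452 with an estimated correlation). Usp18, a brake on interferon signalling, was at 16.9 ± 3.57 against 36.1 ± 3.82 CPM, and the RNA sensor Oas1a at 49.4 ± 0.55 against 85.7 ± 13.5. Double-strand break repair genes had a median of 0.77 over 30, with 9 higher over the list alone (camera adjusted p = 5.04e-07; adjusted p = 0.463 with an estimated correlation), and the histone H2ax was at 83.0 ± 12.5 against 41.1 ± 8.35 CPM. Ribosome biogenesis genes had a median of 0.50 over 29 (camera adjusted p = 5.53e-05; adjusted p = 0.463 with an estimated correlation). Markers of other cells moved with the label as well. Fibroblast markers had a median of 2.75 over 11, with 8 higher over the list alone, and B and plasma cell markers a median of 1.47 over 12 (camera adjusted p = 0.000183 and 0.000164; adjusted p = 0.463 for both with an estimated correlation). The collagen Col3a1 was at 10.7 ± 10.0 against 0.918 ± 0.59 CPM. Tuft and enteroendocrine markers also passed camera upward (adjusted p = 0.0002 and 0.00326; adjusted p = 0.452 for both with an estimated correlation). The tuft cell G protein subunit Gnat3 stood at 1.6 ± 0.326 against 0.477 ± 0.119 CPM. Upward calls for Paneth, T/NK, Hox and extracellular matrix lists (adjusted p = 0.00531, 0.029, 0.0325 and 0.0423; adjusted p = 0.554, 0.61, 0.463 and 0.463 with an estimated correlation) were each lost without 1 or more of the WT libraries. They had adjusted p = 0.0693 to 0.145 without WT replicate 2 for the T/NK, Hox and extracellular matrix lists. Paneth markers had 0.052 without WT replicate 1 and 0.0755 without replicate 3, Hox genes 0.103 without WT replicate 3 and 0.0731 without Rad21+/- replicate 3, and extracellular matrix genes 0.052 without WT replicate 1. The T/NK list turned downward without Rad21+/- replicate 4, at adjusted p = 0.88, and with the replicate number as a block, at 0.835. With a term for Y-linked transcripts the Hox and Paneth calls were lost (0.0929 and 0.0702). The other 11 lists had adjusted p from 0.0549 to 0.467, among them 19 cohesin factors at a median of 0.15 (0.0995). For the goblet and MHC class II lists the median was below 0 and the mean above it.

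Of 12585 tested transcripts, edgeR called 0 between Rad21+/- and WT crypts, with 3723 at an unadjusted p under 0.05, and DESeq2 called 1697 (700 higher, 997 lower). In 4618 transcripts the groups did not overlap, where chance gives 10%. Rad21 had a log2 fold change of 0.20 ± 0.16 (adjusted p = 0.397) and Apc of -0.36 ± 0.18 (adjusted p = 0.212), which became 0.07 with total counts as the scale. That scale moved the median of all transcripts up by 0.45. Without Rad21+/- replicate 2 edgeR called 1693 genes, without replicate 4 it called 3, and with all groups in 1 fit 1372. Fabp1, Cyp3a11, Mttp, Plk1, Ube2c, Axin2, Sox9, Sp5, Usp18, Oas1a, H2ax, Col3a1 and Gnat3 passed without Rad21+/- replicate 2, at adjusted p from 0.0199 to 0.0496.

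Apc Min crypts were compared with WT crypts to ask how crypt expression differs with the Apc Min label. The largest group difference was in interferon-stimulated genes, where 22 of 33 were lower when adjusted over the list alone and the median was -0.95 (camera adjusted p = 3.46e-61; adjusted p = 0.11 with an estimated correlation). The RNA sensors Oas3 (56.1 ± 6.5 against 128 ± 19.6 CPM) and Oas1a (34.1 ± 3.63 against 74.4 ± 12.4), their relative Oasl2 (98.1 ± 9.32 against 210 ± 32.8) and Usp18 (12.7 ± 1.67 against 31.3 ± 3.56) were lower without overlap of the groups, with adjusted p of 0.0626 for all but Oas1a, at 0.0718. The ileal bile acid binding protein Fabp6 was at 145 ± 25.5 against 485 ± 201 CPM (log2 -1.74 ± 0.32, adjusted p = 0.307). This gene belongs to an enterocyte list with a median of -0.16 over 39 genes and 1 lower over the list alone (camera adjusted p = 5.73e-06; adjusted p = 0.81 with an estimated correlation). Nos2, an inducible source of nitric oxide, was at 110 ± 112 against 34.8 ± 13.7 CPM. This gene belongs to an antimicrobial list with a median of 0.91 over 13 genes and none past its own adjustment (camera adjusted p = 0.00037; adjusted p = 0.5 with an estimated correlation). Anxa1, a fetal-like gene, was at 0.913 ± 0.0649 against 0.109 ± 0.0664 CPM, and 2 of 17 genes of its list were higher over the list alone at a median of 0.15 (camera adjusted p = 0.0132; adjusted p = 0.385 with an estimated correlation). Ribosome biogenesis and enteroendocrine lists passed camera upward with medians of 0.13 and 0.15 (adjusted p = 0.00148 and 0.0126; adjusted p = 0.984 and 0.81 with an estimated correlation).

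Wnt targets had a median of -0.01 over 18 genes, opposite to the direction of camera (adjusted p = 0.967). Axin2 stood at 56.5 ± 6.18 against 60.1 ± 12.7 CPM and Lgr5 at 7.06 ± 1.42 against 8.88 ± 5.38. Without WT replicate 2 the log2 fold changes of Axin2 and Lgr5 turned from -0.09 and -0.33 to 0.08 and 0.15. Stem cell genes (adjusted p = 0.368), cell cycle genes (0.667) and cohesin factors (0.362) did not pass either, and all 16 lists below the threshold had adjusted p from 0.267 to 0.967. Rad21 had a log2 fold change of -0.13 ± 0.11 (adjusted p = 0.928) and Apc of 0.11 ± 0.08 (adjusted p = 0.913). Of 11784 tested transcripts edgeR called 0, with 727 at an unadjusted p under 0.05 and 1320 without overlap of the groups, where chance gives 10%. DESeq2 called 62 (8 higher, 54 lower), limma on the deposited log2 values 0 (810 at an unadjusted p under 0.05) and edgeR without a filter 8. Leaving out WT replicate 3 gave 252 genes, among them Usp18, Oas3, Oasl2, Oas1a, Fabp6 and Anxa1 at adjusted p from 0.000639 to 0.0413, and leaving out Apc Min replicate 1 gave 1. The list count of 6 rose to 13 without WT replicate 2, while without WT replicate 3 the enterocyte, ribosome, enteroendocrine and fetal-like calls were lost (adjusted p = 0.202, 0.919, 0.303 and 0.196). The fetal-like call was also lost without WT replicate 1 (0.0939) and Apc Min replicate 1 (0.105), the enteroendocrine call without Apc Min replicates 1 (0.123) and 3 (0.189), and the ribosome call without Apc Min replicate 3 (0.189). WT replicate 3 is the WT library with Y-linked transcripts, which all 3 Apc Min crypt libraries hold. A term for these transcripts sets WT replicate 3 alone against the Apc Min crypts. With it the antimicrobial list turned downward and the fetal-like call was lost, on a single WT library.

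**Figure D3:**
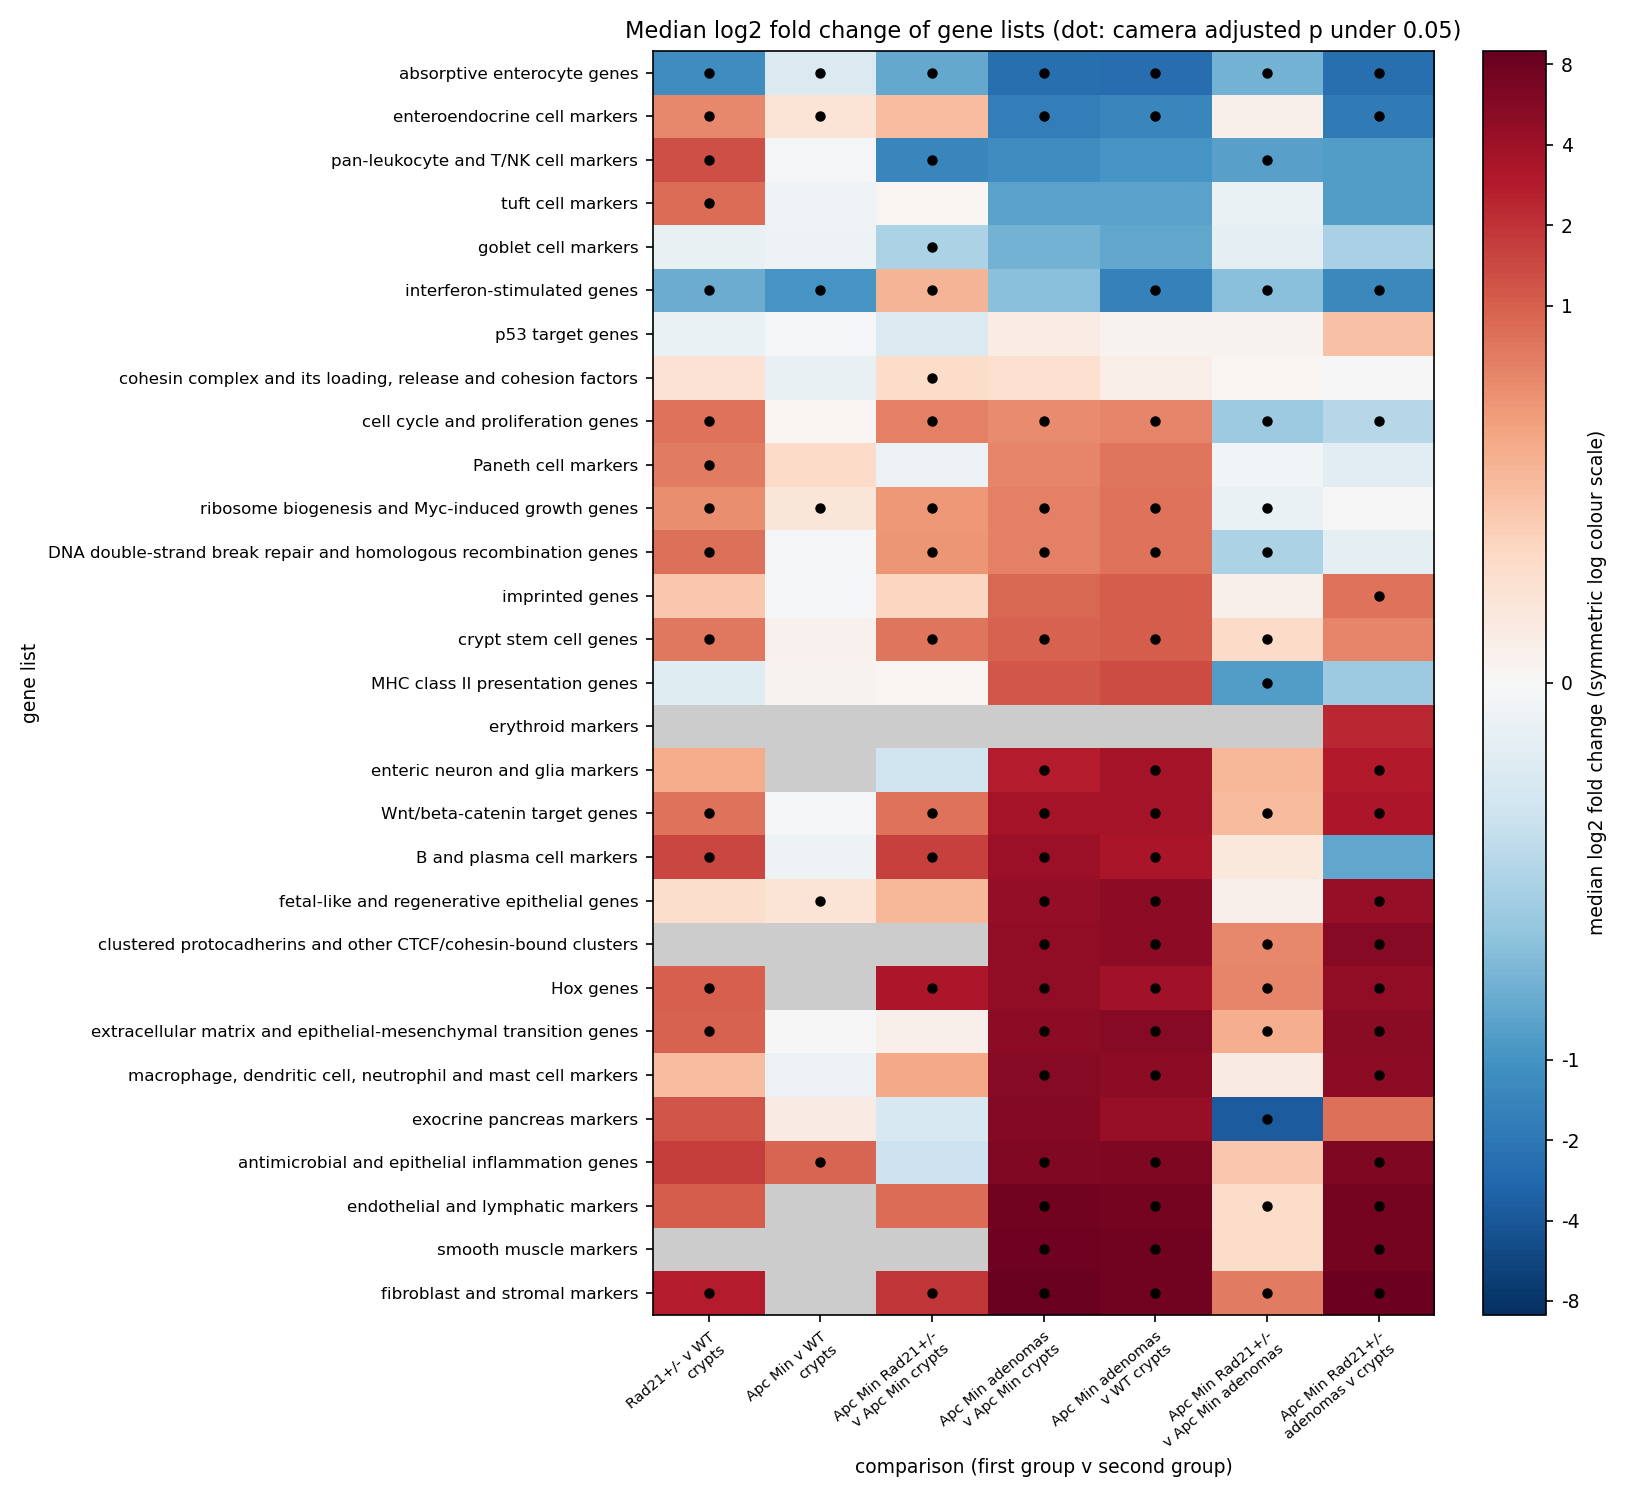
Median log2 fold change of each gene list (colour, symmetric log scale) in the 7 comparisons, with genes at 0 in a group set to their bound; dots mark lists past the camera threshold with a correlation of 0.01, and grey marks lists with fewer than 5 tested genes. Enterocyte genes have medians from -2.49 to -0.16, below 0 in all 7 comparisons.

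Apc Min Rad21+/- crypts were compared with Apc Min crypts to ask what differs with the Rad21 label in crypts labelled Apc Min. Absorptive enterocyte genes fell: 29 of 39 were lower and 2 higher, 32 and 2 when adjusted over the list alone, with a median of -0.62 (camera adjusted p = 1.27e-11; adjusted p = 0.383 with an estimated correlation). The basolateral glucose transporter Slc2a2 went from 1000 ± 74.3 to 521 ± 27.4 CPM (log2 -0.95 ± 0.08, adjusted p = 0.000274) and the retinol carrier Rbp2 from 5440 ± 472 to 2580 ± 217. Cell cycle genes rose in 28 of 31 cases over all genes and over the list alone, with a median of 0.61 (camera adjusted p = 3.34e-13; adjusted p = 0.465 with an estimated correlation). The replication licensing factor Cdt1 (43.1 ± 1.58 against 27.3 ± 0.732 CPM, adjusted p = 0.000417) and the mitotic cyclins Ccnb1 (24.1 ± 1.26 against 12.6 ± 1.72) and Ccnb2 (66.4 ± 3.38 against 37.1 ± 3.98) were among them. Stem cell genes rose in 12 of 17 cases, 13 over the list alone (camera adjusted p = 2.05e-07; adjusted p = 0.383 with an estimated correlation). Lgr5 stood at 16.2 ± 2.93 against 7.79 ± 1.57 CPM (log2 1.06 ± 0.18, adjusted p = 0.00241), the chloride cotransporter Slc12a2 at 381 ± 13.5 against 182 ± 22.4 and the matricellular Smoc2 at 113 ± 7.72 against 69.2 ± 6.32. Of 19 Wnt targets 13 rose and 1 fell, over all genes and over the list alone (camera adjusted p = 9e-06; adjusted p = 0.383 with an estimated correlation). Cyclin D1 (Ccnd1) rose by 1.13 ± 0.11, the receptor Ephb2 by 0.77 ± 0.08 and Axin2 by 0.55 ± 0.12, while Sp5 fell by 0.80 ± 0.13 on the log2 scale.

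Ribosome biogenesis genes rose in 21 of 29 cases and 1 fell, 22 and 1 over the list alone (camera adjusted p = 1.57e-07; adjusted p = 0.465 with an estimated correlation). Among them were the nucleolar proteins Npm1 (159 ± 5.67 against 89.8 ± 10.2 CPM) and Ncl (587 ± 17.0 against 356 ± 27.5). Double-strand break repair genes rose in 16 of 30 cases, 17 over the list alone (camera adjusted p = 1.85e-05; adjusted p = 0.465 with an estimated correlation). The histone H2ax stood at 72.0 ± 2.04 against 42.0 ± 5.48 CPM. Cohesin factors rose in 9 of 19 cases with none falling, in both adjustments (camera adjusted p = 0.0221, 0.465 with an estimated correlation). These included Cdca5, which protects cohesin on chromosomes (20.2 ± 1.4 against 10.9 ± 0.782 CPM), the acetyltransferase Esco2 (20.7 ± 0.66 against 12.4 ± 2.47) and the core subunit Smc3 (84.1 ± 3.58 against 61.7 ± 4.11). Rad21 itself rose from 233 ± 5.89 to 294 ± 9.98 CPM (log2 0.34 ± 0.07, adjusted p = 0.00422). Apc fell from 212 ± 10.6 to 157 ± 13.8 CPM (adjusted p = 0.00367), a fall that did not pass with total counts as the scale (0.109). Interferon-stimulated genes rose in 16 of 33 cases and fell in 4, 17 and 4 over the list alone (camera adjusted p = 0.000719; adjusted p = 0.465 with an estimated correlation). The antiviral GTPase Irgm1 stood at 69.2 ± 7.34 against 34.1 ± 1.78 CPM, the tether Bst2 at 19.6 ± 4.01 against 8.83 ± 0.376 and Oas1a at 74.7 ± 15.3 against 37.7 ± 4.0.

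Markers of immune and stromal cells moved apart in the Apc Min Rad21+/- crypts. T/NK markers fell in 11 of 17 cases and rose in 1, 11 and 2 over the list alone, with a median of -1.35 (camera adjusted p = 1.85e-05; adjusted p = 0.465 with an estimated correlation). The surface receptor Cd7 went from 25.2 ± 4.38 to 7.58 ± 0.422 CPM and the granzyme Gzma from 104 ± 25.1 to 35.3 ± 4.54. B and plasma cell markers rose in 10 of 11 cases, in both adjustments (camera adjusted p = 0.0001, 0.383 with an estimated correlation). The immunoglobulin joining chain Jchain stood at 8.91 ± 1.78 against 3.87 ± 0.721 CPM. Of 27 fibroblast markers 9 were tested, 7 rose and 1 fell, in both adjustments (camera adjusted p = 0.00889, 0.383 with an estimated correlation). Col3a1 rose by 2.08 ± 0.39 to 2.18 ± 0.282 CPM, and the matrix protein Fbln1 fell by 0.51 ± 0.10. Of 32 Hox genes 5 were tested and 4 rose, in both adjustments (camera adjusted p = 0.00308, 0.465 with an estimated correlation). Hoxb9 stood at 1.58 ± 0.608 against 0.112 ± 0.121 CPM, and Hoxb8, at 3 counts in Apc Min crypts, had a ratio of 13.4 (95% interval 4.4 to 66.2). Goblet markers fell in 8 of 17 cases and rose in 2, in both adjustments (camera adjusted p = 0.018, 0.534 with an estimated correlation). The secreted Clca1 stood at 896 ± 115 against 1870 ± 83.9 CPM and the mucus protein Fcgbp at 2770 ± 147 against 4770 ± 170. That call was lost without Apc Min replicate 3 (0.087) or Apc Min Rad21+/- replicate 4 (0.142), and with the replicate number as a block (0.183). Paneth markers had 3 higher and 1 lower of 20, 0 and 1 over the list alone. Their median was -0.06 (0.20 with total counts as the scale), with a mean above 0 and a camera adjusted p of 0.778. Tuft markers (0.896), p53 targets (0.152), enteric neuron markers (0.981) and imprinted genes (0.699) were among the 13 lists that did not pass, at 0.0945 to 0.981.

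The largest falls were of the stress chaperones Hspa1a, from 21 ± 12.6 to 0.338 ± 0.105 CPM (log2 -5.93 ± 0.60, adjusted p = 0.000357), and Hspa1b, from 45.4 ± 24.5 to 2.27 ± 0.371. Next came the cytochrome P450 genes Cyp1a1 (log2 -4.01 ± 0.97, adjusted p = 0.011, and 0.0637 by DESeq2), Cyp2c29, from 427 ± 49.2 to 47.7 ± 26.6 CPM, Cyp2b9 and Cyp2b13. The fasting-responsive Pdk4, Angptl4, the lectin Mbl2 and the sulfate donor synthase Papss2 completed the 10, with log2 fold changes from -2.34 to -2.14. Among the 10 largest rises, the beta globin Hbb-bs went from 3.56 ± 1.22 to 91.6 ± 84.0 CPM (log2 4.67 ± 0.65, adjusted p = 0.00102), Lrg1 from 0.397 ± 0.32 to 3.26 ± 2.79 (adjusted p = 0.0152, and 0.0515 without Apc Min replicate 1). The inositol transporter Slc2a13 went from 0.627 ± 0.0833 to 3.16 ± 0.766 and Ifi44, an interferon-induced gene, from 3.55 ± 0.827 to 14.5 ± 3.23. Slfn5, Cyp2e1, Ly6a, Phf11d, Oas2 and Dpysl5 rose by 1.82 to 2.13 on the log2 scale.

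Of 12395 tested transcripts edgeR called 4908 between Apc Min Rad21+/- and Apc Min crypts, 2483 higher and 2425 lower, and in 6474 the groups did not overlap, where chance gives 10%. Changes of at least 2-fold were fewer, at 354 higher and 377 lower. With total counts as the scale, which moved the median of all transcripts up by 0.25, 6004 passed and the share of rises went from 50.6% to 84.0%. A fit of all groups with deposited counts shared 1 estimate of spread and called 15 genes, 2 higher and 13 lower. None of the genes named for this comparison passed in it, at adjusted p from 0.052 to 0.403.

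**Figure D4:**
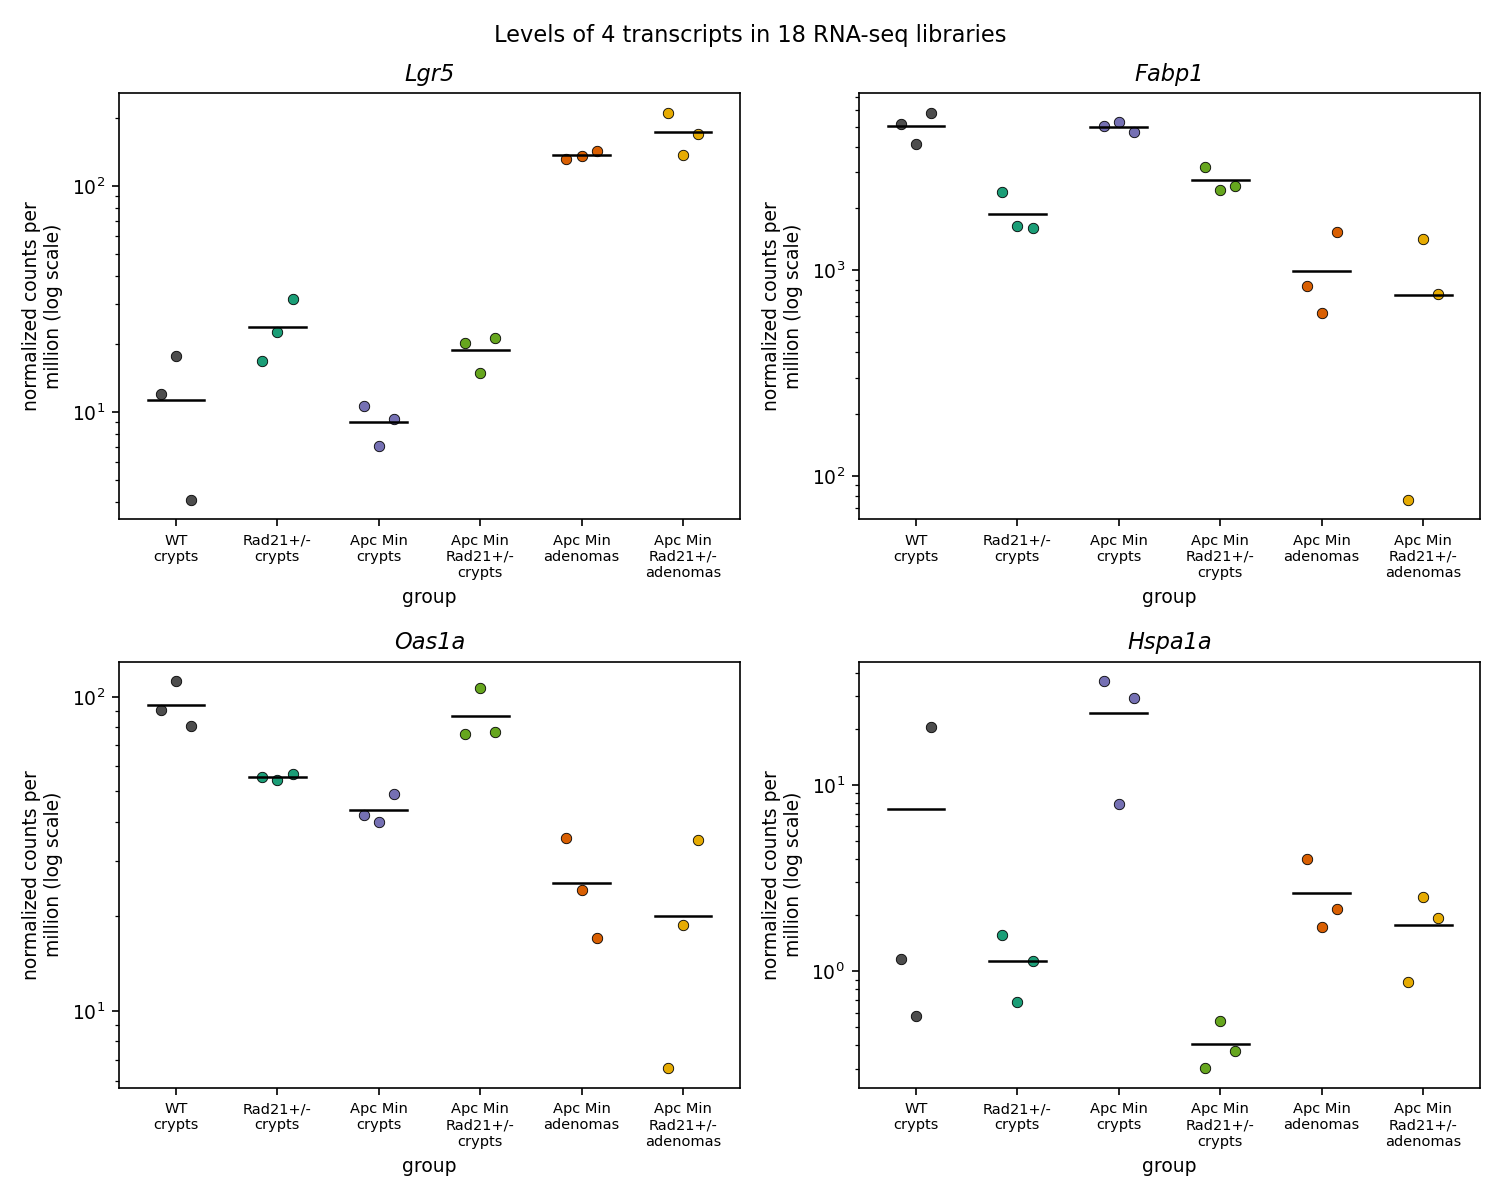
NormalizedCPM (log scale) of the stem cell gene Lgr5, the enterocyte gene Fabp1, the interferon-stimulated Oas1a and the chaperone Hspa1a in each of the 18 RNA-seq libraries (points), with group means (lines, n = 3). Mean Oas1a is 94.5 in WT, 55.6 in Rad21+/-, 43.6 in Apc Min and 86.6 in Apc Min Rad21+/- crypts; mean Hspa1a is 24.3 in Apc Min and 0.405 in Apc Min Rad21+/- crypts.

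The fold changes for the Rad21+/- label in crypts with and without Apc Min, which share no library, were compared across genes. Over 12213 transcripts tested in both, the changes had Pearson r = 0.544 and Spearman rho = 0.624, and 75.9% had the same sign. Pearson r was 0.337 without WT replicate 3, 0.333 by DESeq2, 0.303 without a filter and 0.4 with all groups in 1 fit. Genes are not independent replicates, so these values describe and do not test. Among the 4876 of them called with Apc Min, 90.2% had the same sign without it. EdgeR shared 0, as none passed without Apc Min. By DESeq2, of 17616 genes 402 were higher in both, 704 lower (91.0 and 139.7 by chance) and 18 opposite. Without Rad21+/- replicate 2 edgeR shared 376 higher and 756 lower genes (116.8 and 210.9 by chance), and 1 without replicate 4. Chance assumes independent, equally callable genes. Depth follows the label in both pairs, so a shared batch is possible.

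Apc Min adenomas were compared with Apc Min crypts to describe how dissected tumours differ from EDTA-released crypts. Wnt targets rose in 25 of 26 cases and 1 fell, over all genes and over the list alone, with a median log2 fold change of 3.53 (camera adjusted p = 3.72e-07; adjusted p = 0.146 with an estimated correlation). The Wnt inhibitors Notum (304 ± 124 against 0.724 ± 0.427 CPM), Dkk3 (152 ± 57.9 against 0.208 ± 0.0195), Wif1 (205 ± 66.6 against 0.263 ± 0.232) and Nkd1 (42.6 ± 15.7 against 0.166 ± 0.108) rose. Their relative Dkk2, at 0 counts in crypts, was at least 462-fold higher than a floor of 3 counts over the group, and Axin2 went from 66.5 ± 7.01 to 185 ± 55.7. Cyclin D2 (Ccnd2) fell by 0.53 ± 0.11 (adjusted p = 0.00304) but was higher by 0.16 with total counts as the scale. Stem cell genes rose in 13 of 18 cases and fell in 2, in both adjustments (camera adjusted p = 0.0129; adjusted p = 0.339 with an estimated correlation). Lgr5 went from 8.34 ± 1.65 to 126 ± 4.87 CPM (log2 3.94 ± 0.15, adjusted p = 7.51e-07) and the growth factor binding protein Igfbp4 from 23.2 ± 3.67 to 463 ± 118, while Clca3b fell from 418 ± 71.0 to 150 ± 82.8. Fetal-like epithelial genes rose in 21 of 23 cases, 22 over the list alone, with a median of 4.75 (camera adjusted p = 1.92e-08; adjusted p = 0.138 with an estimated correlation). The secreted chaperone Clu went from 4.17 ± 1.2 to 2840 ± 789 CPM (log2 9.42 ± 0.25), Anxa1 from 1.1 ± 0.0749 to 278 ± 42.8 and the surface protein Ly6d from 1.9 ± 0.642 to 142 ± 7.92. Enterocyte genes fell in 36 of 39 cases and 1 rose, in both adjustments, with a median of -2.36 (camera adjusted p = 4.2e-11; adjusted p = 0.138 with an estimated correlation). Among them were the peptidase Dpp4 (84.6 ± 2.33 against 743 ± 60.8 CPM), the peptide transporter Slc15a1 (130 ± 8.82 against 1300 ± 179) and Mttp (21 ± 3.57 against 139 ± 12.5). Enteroendocrine markers fell in 16 of 19 cases and 1 rose, in both adjustments (camera adjusted p = 0.000405; adjusted p = 0.274 with an estimated correlation). The hormone Sct stood at 10.9 ± 1.29 against 40.5 ± 6.75 CPM and the lineage factor Neurog3 at 0.735 ± 0.0972 against 4.76 ± 0.181.

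Markers of cells that dissected tissue holds and EDTA-released crypts largely lack rose in the Apc Min adenomas beside these groups. Fibroblast markers rose in 21 of 22 cases and 1 fell, with a median of 8.54 (8.43 with genes at 0 set to their bound). Extracellular matrix genes rose in 18 of 20 and 1 fell, with a median of 5.09, and endothelial markers rose in 13 of 13, with a median of 7.42. All 3 counts held in both adjustments (camera adjusted p = 7.48e-08, 5.5e-07 and 3.49e-06; adjusted p = 0.0883, 0.107 and 0.138 with an estimated correlation). Fibronectin (Fn1) went from 0.39 ± 0.0283 to 187 ± 29.7 CPM, the collagens Col1a1 from 0.173 ± 0.0567 to 147 ± 13 and Col3a1 from 0.566 ± 0.375 to 293 ± 30.9, and the vascular Plvap from 0.114 ± 0.0747 to 39.0 ± 4.54. The endothelial receptor Kdr was at least 406-fold higher. Macrophage to mast cell markers rose in 24 of 26 cases and 1 fell, with a median of 5.58 (camera adjusted p = 6.4e-07; adjusted p = 0.146 with an estimated correlation). The complement gene C1qb stood at 37.9 ± 1.98 against 0.438 ± 0.0557 CPM and the neutrophil protein S100a9 at least 216-fold higher. Smooth muscle markers rose in 8 of 10 cases and 1 fell, with a median of 8.12 (7.65 with bounds), B and plasma cell markers in 5 of 7, with a median of 4.10, and enteric neuron markers in 8 of 9, with a median of 2.80. Counts were equal over the lists alone (camera adjusted p = 0.00309, 0.0168 and 0.00682; adjusted p = 0.274, 0.146 and 0.146 with an estimated correlation). Jchain went from 4.16 ± 0.785 to 742 ± 57.3 CPM, the contractile Tagln from 5.04 ± 0.654 to 83.2 ± 9.97 and Ret, a receptor of enteric neurons, from 0.949 ± 0.136 to 6.38 ± 1.56. Cnn1 was at least 396-fold higher. T/NK markers (7 higher, 9 lower of 16), exocrine pancreas markers (4 higher, 1 lower of 18, median 5.71) and MHC class II genes did not pass, at adjusted p = 0.416, 0.136 and 0.134. The pancreatic trypsinogen Prss2 stood at 63.1 ± 101 CPM on the joint scale in Apc Min adenomas.

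Antimicrobial and inflammation genes rose in 17 of 25 cases and fell in 4, in both adjustments, with a median of 6.61 (5.99 with bounds; camera adjusted p = 0.00211; adjusted p = 0.339 with an estimated correlation). The cytokine Il11 went from 0.193 ± 0.0374 to 19.5 ± 7.75 CPM. Hox genes rose in 16 of 16 cases, with a median of 4.87, and clustered protocadherins, whose promoters cohesin and CTCF bind, in 9 of 10, with a median of 4.91 (4.79 with bounds). Both counts held over the list alone (camera adjusted p = 0.000234 and 0.000848; adjusted p = 0.12 and 0.146 with an estimated correlation). Hoxa3 stood at 6.47 ± 2.49 against 0.298 ± 0.0224 CPM and Pcdhgc3 at 24.3 ± 3.7 against 1.54 ± 0.206. Cell cycle genes rose in 21 of 29 cases, ribosome biogenesis genes in 20 of 28 with 1 falling and double-strand break repair genes in 19 of 28 with 2 falling. These counts held in both adjustments (camera adjusted p = 0.00305, 0.0109 and 0.0213; adjusted p = 0.685 for each with an estimated correlation). The spindle checkpoint protein Mad2l1 went from 22.4 ± 4.27 to 50.0 ± 4.95 CPM, Npm1 from 95.9 ± 11 to 242 ± 1.17 and the repair factor Fancd2 from 5.93 ± 0.203 to 14.9 ± 4.41. With a term for Y-linked transcripts the cell cycle and repair calls were lost (0.0565 and 0.177). Cohesin factors did not pass as a list (0.677), with 6 higher and 3 lower of 19 in both adjustments: Smc3 rose by 0.38 ± 0.08, and the release factor Wapl fell by 0.62 ± 0.09 but was higher by 0.06 with total counts as the scale. Apc fell by 0.44 ± 0.11 (adjusted p = 0.00659) and was higher by 0.25 with total counts as the scale, and Rad21 had -0.07 ± 0.07 (adjusted p = 0.378) and 0.61 on that scale. Interferon-stimulated genes (7 higher, 15 lower of 32; adjusted p = 0.0941) and goblet markers (6 higher, 8 lower of 17, 6 and 9 over the list alone; 0.142) had medians of -0.44 and -0.51, which turned to 0.24 and 0.18 on that scale. Tuft (0.272), Paneth (0.693), imprinted (0.117) and p53 target (0.978) lists did not pass.

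The largest single rises were of Serpina3n, a protease inhibitor of the acute phase, and the matrix metalloproteinase Mmp10, with 3 and 2 counts in Apc Min crypts and ratios of 8050 (95% interval 2750 to 39000) and 7070 (1960 to 58400). Mmp13 and the proteoglycan Bgn, with 3 counts each in crypts, had ratios of 1960 (670 to 9500) and 1690 (577 to 8190). The collagen Col4a2 reached 139 ± 21.1 CPM, Igfbp5 216 ± 17.6, the amino acid transporter Slc38a4 572 ± 49.6, the matrix protein Tnc 90.0 ± 21.1 and Wfdc18 397 ± 91.2, from 0.451 ± 0.259 CPM or less. The cytochromes Cyp2c29 (456 ± 53.5 to 1.58 ± 1.26 CPM), Cyp2b10 (2000 ± 253 to 43.7 ± 22.3) and Cyp2b13 were among the largest falls. So were the vitamin C transporter Slc23a1 (222 ± 43.2 to 5.24 ± 2.36) and the sugar transporters Slc5a4a (176 ± 41.4 to 4.77 ± 2.03) and Slc2a7 (134 ± 3.46 to 3.97 ± 1.64). The other 4 were the Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d, which, at adjusted p from 0.0231 to 0.0306, lost the call without any library other than Apc Min adenoma replicate 3, at 0.0565 to 0.106. Of 12858 transcripts limma called 9075, 5004 higher and 4071 lower, 3189 and 1897 by at least 2-fold, and in 9729 the groups did not overlap, where chance gives 10%. With total counts as the scale, which moved the median of all transcripts up by 0.69, 10232 passed and the share of rises went from 55.1% to 83.2%.

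Apc Min adenomas were also compared with WT crypts. Dissected tumour tissue is set here against EDTA-released crypts, so tumour change and tissue content are not separated. Clu went from 2.43 ± 1.25 to 2840 ± 789 CPM, Anxa1 from 0.152 ± 0.0789 to 278 ± 42.8, Lgr5 from 10.4 ± 6.3 to 126 ± 4.87 (log2 3.83 ± 0.47, adjusted p = 0.000302). Notum went from 0.762 ± 0.47 to 304 ± 124 and the receptor Ephb3 from 7.29 ± 2.39 to 114 ± 12.3. Fetal-like genes rose in 20 of 23 cases (22 over the list alone), Wnt targets in 24 of 26 with 1 falling and stem cell genes in 13 of 18 with 1 falling (camera adjusted p = 5.88e-08, 7.89e-07 and 0.0252; adjusted p = 0.112, 0.307 and 0.65 with an estimated correlation). Enterocyte genes fell in 35 of 39 cases (8.49e-12; adjusted p = 0.114 with an estimated correlation). Dpp4 went from 869 ± 49.5 to 84.6 ± 2.33 CPM. Enteroendocrine markers fell in 15 of 19 (16 over the list alone) with 1 rising (0.000543; adjusted p = 0.284 with an estimated correlation). Interferon-stimulated genes fell in 20 of 32 cases and rose in 4 (0.000338; adjusted p = 0.646 with an estimated correlation). The inducer Irf7 went from 255 ± 31.3 to 70.3 ± 9.04 CPM and Oas3 from 151 ± 22.9 to 8.44 ± 5.01. Fibroblast, macrophage, extracellular matrix and endothelial lists rose with medians of 7.83 (7.57 with bounds), 5.21 (5.11), 5.51 and 7.63 (7.13) (camera adjusted p = 9.04e-08, 8.55e-07, 1.41e-06 and 1.78e-06; adjusted p = 0.114, 0.139, 0.112 and 0.114 with an estimated correlation). Col3a1 went from 0.957 ± 0.598 to 293 ± 30.9 CPM. Protocadherin, Hox, antimicrobial, smooth muscle, neuron and B cell lists passed upward too (adjusted p = 0.00037, 0.00037, 0.000398, 0.00273, 0.00287 and 0.0189; adjusted p = 0.195, 0.114, 0.351, 0.139, 0.139 and 0.307 with an estimated correlation). So did ribosome biogenesis, cell cycle and repair lists, with 19, 15 and 15 genes higher and 21, 11 and 11 over the list alone (0.00417, 0.0119 and 0.0445; adjusted p = 0.65, 0.732 and 0.74 with an estimated correlation). The repair call was lost without WT replicate 1 (0.0677) or 3 (0.137) or adenoma replicate 1 (0.0931) or 2 (0.0737), and the cell cycle call without adenoma replicate 1 (0.0555).

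The remaining 9 lists of this comparison had adjusted p from 0.123 to 0.942, with cohesin factors at 0.886 and goblet markers at a median of -0.65 that turned to 0.07 with total counts as the scale. The largest rises were of Mmp10, with 3 counts in WT crypts and a ratio of 4570 (95% interval 1570 to 22200), Serpina3n, Wfdc18, Anxa1 and the collagen Col4a1, and the largest falls of Cyp2c29, Slc5a4a, Slc23a1, the lactate transporter Slc5a12 and Sypl2. Apc had a log2 fold change of -0.32 ± 0.12 (adjusted p = 0.0441), lost without any library other than Apc Min adenoma replicate 2, at 0.0624 to 0.134, and turned to 0.39 with total counts as the scale. Rad21 had -0.19 ± 0.11 (adjusted p = 0.182), 0.52 on that scale, and passed downward without WT replicate 3 (-0.29, adjusted p = 0.0328). In total limma called 8388 of 12858 transcripts, 4674 higher and 3714 lower, 3188 and 1883 by at least 2-fold, and in 9328 the groups did not overlap, where chance gives 10%. Total counts as the scale moved the median of all transcripts up by 0.71 and the share of rises from 55.7% to 84.4%.

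Apc Min Rad21+/- adenomas were compared with Apc Min adenomas to ask what differs with the Rad21 label in dissected tumours. Fibroblast and matrix genes lay higher and enterocyte genes lower on balance, and no gene passed the test. These lists do not separate the cell content of the dissected pieces from change within cells. The collagen Col3a1 was at 702 ± 169 against 409 ± 38 CPM and the matrix metalloproteinase Mmp2 at 117 ± 17.2 against 63.5 ± 10.2 (log2 0.89 ± 0.18, adjusted p = 0.899). Zeb2, a driver of mesenchymal fate, was at 26.4 ± 3.79 against 15.8 ± 0.714. Fibroblast markers had a median of 0.65 over 22 genes with 3 higher over the list alone, and extracellular matrix genes 0.39 over 20 with 2 higher (camera adjusted p = 6.54e-13 and 7.63e-08; adjusted p = 0.184 and 0.0913 with an estimated correlation). Slc15a1 was at 81.4 ± 9.26 against 182 ± 13.6 CPM (log2 -1.16 ± 0.14, adjusted p = 0.531) and the fatty acid binding protein Fabp2 at 1170 ± 208 against 1960 ± 49.1. This gene belongs to an enterocyte list with a median of -0.52 over 39 and 3 lower over the list alone (camera adjusted p = 1.39e-13; adjusted p = 0.318 with an estimated correlation). Upward calls also came for protocadherins (median 0.53, 0.000145), Hox genes (0.55, 0.000369), Wnt targets (0.34, 0.0124), stem cell genes (0.20, 0.0156) and endothelial markers (0.19, 0.0295), with adjusted p = 0.562, 0.184, 0.66, 0.409 and 0.66 with an estimated correlation. Downward calls came for cell cycle genes (median -0.39, 1.04e-05), pancreas markers (-3.63, 0.000106), MHC class II genes (-0.81, 0.000106), interferon-stimulated genes (-0.44, 0.000433), T/NK markers (-0.75, 0.00913), repair genes (-0.34, 0.0255) and ribosome biogenesis genes (-0.07, 0.0369). These had adjusted p = 0.66, 0.66, 0.66, 0.664, 0.66, 0.755 and 0.755 with an estimated correlation.

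Single libraries decided many of these list calls. Without Apc Min Rad21+/- replicate 1, cell cycle, repair and ribosome lists turned upward (adjusted p = 0.897, 0.0795 and 0.165), and Wnt, interferon, T/NK and MHC class II calls were lost (0.165, 0.437, 0.56 and 0.0902). Without Apc Min replicate 1, Wnt, interferon, T/NK, repair, ribosome and endothelial calls were lost (0.366, 0.493, 0.149, 0.319, 0.366 and 0.493), and without replicate 2 the repair call (0.124). Apc Min replicate 3 decided the pancreas and stem cell calls (0.425 and 0.191 without it), and Apc Min Rad21+/- replicate 3 the stem cell and endothelial calls (0.119 and 0.13), the latter also lost without replicate 2 (0.226). The groups also differ in sex, with Y-linked transcripts in 1 of 3 Apc Min and 3 of 3 Apc Min Rad21+/- adenoma libraries. With a term for these transcripts, interferon and repair lists turned upward. Cell cycle, Wnt, T/NK, ribosome and endothelial calls were lost with it. The term sets Apc Min replicate 3 alone, which holds Xist as well, against the Apc Min Rad21+/- adenomas. These changes therefore rest on that library. The pancreatic enzyme gene Cpb1 was at 69.8 ± 109 CPM in Apc Min adenomas and 1.02 ± 1.45 in the Apc Min Rad21+/- adenomas. The other 13 lists had adjusted p from 0.0557 to 0.904, with cohesin factors at 0.784. Limma called 0 of 12858 transcripts, with 384 at an unadjusted p under 0.05 and 1260 without overlap of the groups, where chance gives 10%. DESeq2 called 38 (23 higher, 15 lower), Slc15a1, Fabp2, Mmp2 and Zeb2 among them, edgeR on recovered counts called 0 (403 at an unadjusted p under 0.05), and limma called 5 without Apc Min replicate 3. Rad21 had 0.02 ± 0.15 (adjusted p = 0.973), Apc 0.14 ± 0.18 and Lgr5 0.32 ± 0.19. Without Apc Min Rad21+/- replicate 1 the Rad21 and Apc values became -0.09 and -0.01.

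Apc Min Rad21+/- adenomas were compared with Apc Min Rad21+/- crypts for the same difference between dissected tumours and EDTA-released crypts with the Rad21 label. Wnt targets rose in 22 of 27 cases, 23 with 1 fall over the list alone (camera adjusted p = 1.26e-08; adjusted p = 0.145 with an estimated correlation). Wif1 went from 0.726 ± 0.263 to 314 ± 61.4 CPM and Sox9 from 29.2 ± 1.05 to 145 ± 15.2. Lgr5 went from 20.7 ± 3.74 to 194 ± 48.0 (log2 3.23 ± 0.24, adjusted p = 0.000127) and Axin2 from 117 ± 15.6 to 309 ± 168 (adjusted p = 0.0187, and 0.0594 to 0.0777 without each of the 3 crypt libraries). Fetal-like genes rose in 24 of 24 cases in both adjustments (1.04e-13; adjusted p = 0.0635 with an estimated correlation). Clu went from 13.3 ± 4.46 to 3720 ± 806 CPM and Anxa3 from 4.85 ± 0.393 to 91.9 ± 5.13. Enterocyte genes fell in 31 of 39 cases, 34 with 1 rise over the list alone (5.01e-16; adjusted p = 0.145 with an estimated correlation). The peptidase Anpep went from 11500 ± 910 to 739 ± 151 CPM and Slc15a1 from 1240 ± 91.5 to 70.2 ± 7.91. Enteroendocrine markers fell in 16 of 22 cases and 1 rose, 17 and 1 over the list alone (1.11e-07; adjusted p = 0.0635 with an estimated correlation): somatostatin (Sst) went from 44.4 ± 7.49 to 9.48 ± 1.63 CPM. By contrast, the lectin Reg4 rose from 123 ± 7.65 to 451 ± 29.3. Interferon-stimulated genes fell in 18 of 33 cases and rose in 4, 21 and 4 over the list alone (0.000181; adjusted p = 0.58 with an estimated correlation). The peptide transporter Tap1 went from 7.92 ± 1.05 to 1.78 ± 0.361 CPM and the GTPase Gbp2 from 2.79 ± 0.121 to 13.3 ± 3.86. Extracellular matrix genes (22 of 24 higher, 23 over the list alone, 1 lower) and Hox genes (21 of 21 higher) were the only lists of any comparison to pass camera with an estimated correlation as well, both at adjusted p = 0.0466. Mmp2 went from 0.0973 ± 0.0456 to 101 ± 14.8 CPM and Hoxa7 from 0.0493 ± 0.0363 to 8.36 ± 1.52.

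Markers of other cells rose in these Apc Min Rad21+/- adenomas too. Fibroblast markers did so in 24 of 25 cases with 1 fall (median 8.08, 8.05 with bounds), endothelial in 15 of 15 (7.74, 7.23), smooth muscle in 10 of 12 (7.84, 7.19) and macrophage to mast cell in 23 of 28 with 1 fall (5.28, 5.04). Their camera adjusted p were 5.01e-16, 2.48e-11, 1.08e-07 and 1.11e-07, with adjusted p = 0.0972, 0.0635, 0.16 and 0.169 with an estimated correlation. Smooth muscle actin (Acta2) went from 0.339 ± 0.0664 to 141 ± 26.2 CPM and the stromal Bmp inhibitor Grem1 from 0.0493 ± 0.0363 to 27.7 ± 3.17. The vascular cadherin Cdh5 went from 0.164 ± 0.0413 to 71.8 ± 7.99 and the macrophage receptor Csf1r from 0.746 ± 0.244 to 38.9 ± 7.43. Protocadherins (15 of 16 higher), antimicrobial genes (17 of 27, 3 lower) and neuron markers (7 of 10) passed upward (8.35e-07, 0.00044 and 0.00151; adjusted p = 0.0972, 0.163 and 0.0972 with an estimated correlation). Pcdhgc3 stood at 38.9 ± 3.49 against 2.36 ± 0.511 CPM and the prostaglandin synthase Ptgs2 at 56.7 ± 1.2 against 0.148 ± 0.135. Imprinted genes rose in 9 of 19 cases, 9 with 1 fall over the list alone (0.0374; adjusted p = 0.163 with an estimated correlation). The imprinted Peg3 stood at 9.71 ± 0.768 against 1.46 ± 0.531 CPM. The call was lost without adenoma replicate 1 (0.125), 2 (0.0612) or 3 (0.0799), and with the replicate number as a block (0.129). Cell cycle genes passed downward with 4 lower and 1 higher of 32, 2 and 0 over the list alone, at a median of -0.31 that turned to 0.15 with total counts as the scale (0.0294; adjusted p = 0.83 with an estimated correlation; 0.458 without adenoma replicate 1; 0.639 with the replicate number as a block). Cdt1 fell by 0.83 ± 0.16, or by 0.37 without passing on that scale. Stem cell genes (10 higher, 2 lower of 18; 0.12) and 5 erythroid markers (2 higher, median 2.37; 0.688), testable in this comparison alone, were among the 13 lists that did not pass, at 0.12 to 0.973.

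The largest rises in Apc Min Rad21+/- adenomas were of genes at 0 counts in the Apc Min Rad21+/- crypts: the laminin Lama1 (at least 472-fold over a floor of 3 counts over the group), the endothelial receptor Adgrl4 (at least 459), Tafa2 (at least 400), the microfibril protein Mfap4 (at least 399) and the neuropeptide Npy (at least 365). The largest falls were of the kidney-type phosphate transporter Slc34a3, with 1 count in adenomas (crypts 652 times higher, 95% interval 116 to 25800), Slc5a4a (172 ± 22.4 to 1.29 ± 1.19 CPM), the potassium channel Kcnj13, Slc23a1 and Slc5a12. Rad21 had -0.37 ± 0.15 (adjusted p = 0.0852), passed downward without adenoma replicate 1 (-0.52, adjusted p = 0.000726), by DESeq2 (-0.41, 0.0316) and with the replicate number as a block (-0.51, 0.00163), and was higher by 0.09 with total counts as the scale. Apc had 0.16 ± 0.17 (adjusted p = 0.466), and -0.02 without adenoma replicate 1. Of 14756 tested transcripts edgeR called 6717, 4118 higher and 2599 lower, 3516 and 1516 by at least 2-fold, and in 9130 the groups did not overlap, where chance gives 10%. Total counts as the scale moved the median of all transcripts up by 0.46 and the share of rises from 61.3% to 83.4%.

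Whether the effect of the Rad21+/- label differed between settings was tested by the interaction contrasts. In crypts, edgeR called 3 of 12993 transcripts for a different effect with Apc Min than without it, all interferon-induced: Ifi44, Oas1g and Oas1a, each with a more positive effect in crypts labelled Apc Min. Between adenomas and crypts with Apc Min, limma called 79 of 12858 transcripts, 30 with a more positive effect in adenomas and 49 with a more negative one, and 616 (38 and 578) with total counts as the scale. The largest of the former were Hspa1a and Hspa1b, and the largest of the latter was Xist, with Y-linked transcripts in 1 of 3 Apc Min adenoma libraries and in all 3 libraries of the other groups. Without Apc Min Rad21+/- adenoma replicate 1 that count was 1019, and without any other library it was 37 or fewer. In crypts the count was 121 without Rad21+/- replicate 2, 28 without WT replicate 3, 10 without Rad21+/- replicate 4 and 1 without WT replicate 1, Rad21+/- replicate 3 or Apc Min replicate 1 or 2.

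Rad21 peaks were listed for 1 ChIP-seq library of WT crypts and 1 of Apc Min adenomas, without replicates, on build mm9. The crypt list held 7927 peaks with scores from 40.01 to 3100 (median 56.9), a median width of 818 bp and 6.64 Mb in all, and the adenoma list 13014 peaks with scores from 30 to 3100 (median 35.4), a median width of 867 bp and 13.3 Mb. Of the crypt peaks 548 (6.91%, exact 95% interval 6.36 to 7.49) overlapped an adenoma peak, and of the adenoma peaks 508 (3.9%, 3.58 to 4.25) overlapped a crypt peak. Crypt peaks moved at random along their chromosomes overlapped in 0.946% of cases (0.681 to 1.25% over 100 shifts). In the highest quartile of crypt peaks by score 8.32% (7.15 to 9.63) overlapped, and in the other quartiles 6.71%, 6.21% and 6.41%. For adenoma peaks the shares were 6.08% (5.29 to 6.96), 3.87%, 2.8% and 2.86%. Among peaks at most 5 kb wide, the top overlapped crypt peaks lay together on chromosome Y, 2779611 to 2896418 (score up to 1057). Peaks in the crypt list alone reached 3100, such as neighbours on chromosome 2 at 98501919 and 98506179. The top in the adenoma list alone lay on chromosome 9 at 115058412 (1242). Mapping artefacts were not tested. Depth of the ChIP libraries is unknown from the peak lists, and the scores depend on it.

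**Figure D5:**
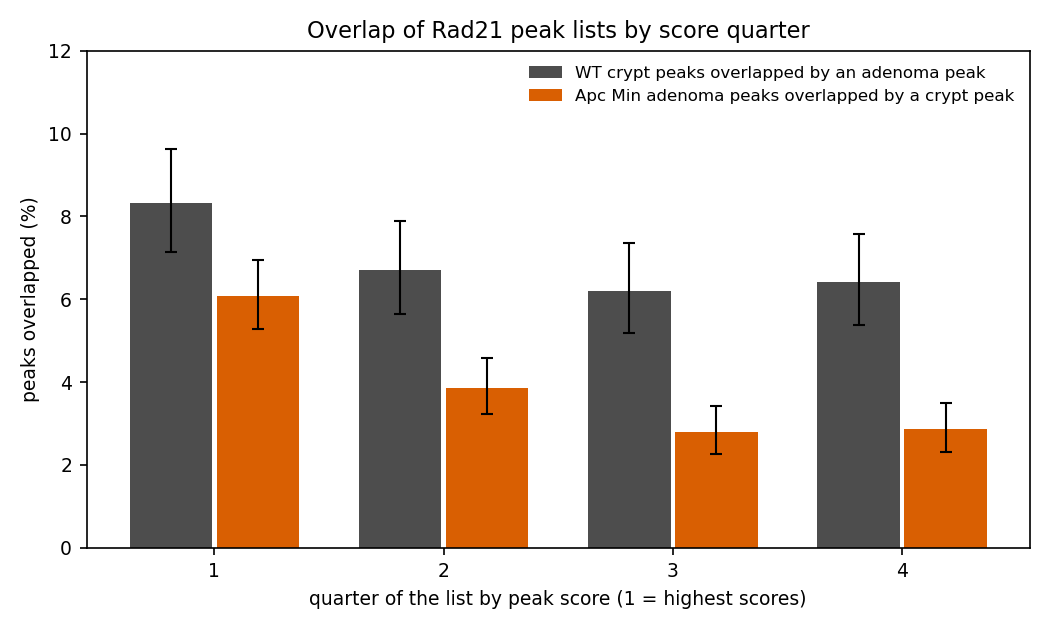
Share of Rad21 peaks in each list overlapped by at least 1 bp by a peak of the other list (percent), by quartile of the list from the highest to the lowest score; lines are exact 95% binomial intervals. The share is 8.32% in the highest quartile of crypt peaks and 6.08% in the highest quartile of adenoma peaks.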

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

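In this part, thinning to the mean total of the partner group, the common peak score, the tests of cell composition and both tests of Rad21 RNA were chosen after seeing the data. What thinning, peak scores and other splits should show was written before those tests were run. For cell composition and both tests of Rad21 RNA it was written after.

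A different effect of the Rad21+/- label by Apc genotype in crypts was called for 3 of 12993 transcripts. Interferon genes were not tested as a list for this contrast. The edgeR interaction was 2.97 for Ifi44 (adjusted p = 0.0468), 2.02 for Oas1g (0.00224) and 1.79 for Oas1a (0.0194). On the joint scale Oas1g, an RNA sensor of the Oas1 cluster, stood at 36.4 ± 6.67 CPM in WT, 19.6 ± 0.872 in Rad21+/-, 14.7 ± 1.1 in Apc Min and 31.5 ± 2.58 in Apc Min Rad21+/- crypts, n = 3 each. With total counts as the scale none of the 3 passed (adjusted p = 0.191, 0.118 and 0.191). Ifi44 lost the call without any of 7 libraries, at 0.077 to 0.27, and Oas1a without WT replicate 1, Rad21+/- replicate 3 or Apc Min replicate 1 or 2, at 0.0727 to 0.127. Of 100 splits that exchange libraries between groups with and without the Rad21 label, the real one included, 3 called at least the real 3 genes and the highest called 3237. Both other splits kept the Apc Min Rad21+/- and Apc Min crypts whole and mixed the rest, so they still carry the difference between those groups.

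In the tissue interaction with Apc Min, limma gave more positive effects in adenomas for Hspa1a (5.08, adjusted p = 0.0399), Hspa1b (4.23, 0.0377), the adhesion molecule Mcam (2.13, 0.0377), the glutathione transferase Gsta4 (2.09, 0.0377) and Tnfaip2 (2.09, 0.0487). More negative effects were those of Xist (-11.73, 0.00256), the heme binding Hebp2 (-1.90, 0.0487), the matricellular Thbs1 (-1.78, 0.0399), the collagen Col16a1 (-1.74, 0.0487) and the membrane protein Emp2 (-1.70, 0.0399). With the replicate number as a block none passed, at 0.164 to 0.2, and all but Xist lost the call without any of 9 or more single libraries, at 0.05 to 0.149. Of 100 such splits 7 called at least the real 79 genes and the highest called 742, so chance is not excluded. The other 6 kept the Apc Min Rad21+/- and Apc Min crypts whole as well, which leaves the difference between them in the contrast. The Rad21 transcript had an interaction of 0.13 ± 0.15 (adjusted p = 0.785) with Apc genotype and -0.33 ± 0.14 (0.24) with tissue, which passed without Apc Min Rad21+/- adenoma replicate 1 (-0.43, 0.0221). Apc had -0.08 ± 0.19 (0.91) and 0.57 ± 0.19 (0.162).

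Lower enterocyte genes and higher proliferation genes in Apc Min Rad21+/- crypts than in Apc Min crypts have several possible sources. Library depth as the whole source is argued against: with Apc Min Rad21+/- libraries thinned to the Apc Min mean total 4772 genes passed, and enterocyte and cell cycle lists had medians of -0.61 and 0.63 (camera adjusted p = 2.24e-11 and 7.33e-14 at the preset correlation; without thinning, an estimated one gave 0.383 and 0.465). Fewer enterocytes with other cells in unchanged proportion would leave stem cell and goblet markers level. Their medians differed by 1.04 (95% bootstrap interval over genes taken as independent 0.469 to 1.34). Per library the difference was 0.268 to 0.777 in Apc Min Rad21+/- crypts against -0.478 to -0.461, relative to the mean of the 6. The exact p of 0.1 is the lowest possible and not decisive. More crypt base would raise Paneth with stem cell markers. The Paneth median differed by -0.761 over genes (-1.03 to -0.32). Libraries overlapped, at -0.684 to 0.14 against -0.638 to 0.875 (exact p = 0.4). Fewer enterocytes, more crypt base, a larger transit-amplifying share, the genotype and an unlabelled batch that follows the Rad21 label remain possible.

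Rad21 RNA was not lower in the libraries labelled Rad21+/-, for which a lost allele hidden by more proliferating cells is a candidate explanation. Relative to 7 other cohesin core and Ctcf transcripts, Rad21 differed by 0.0745 (0.025 to 0.108 over libraries left out; exact stratified permutation p = 0.21), which argues against a 50% loss of its RNA. Exchanged labels would leave groups without the label at 50% of their partners' level. The lowest of the 3 ratios was 0.79, which argues against that. Both tests assume that 1 allele gives 50% of the RNA. Stable RNA from the targeted allele or compensation by the other was not tested.

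More Rad21 peaks were listed in Apc Min adenomas than in WT crypts, which could follow from the different score limits of the lists. With scores of at least 40 in both, the ratio of adenoma to crypt peak numbers was 0.47, against 1.64 in the full lists. The lists fixed a fall beforehand (lowest crypt score 40.01, adenoma median 35.4), so this cannot decide the cause. Different depth or enrichment of the libraries is also possible and was not tested. At that limit 3.22% of crypt and 5.88% of adenoma peaks were overlapped, against 6.91% and 3.9% in the full lists.

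Groups of 3 allow only 10 splits of 6 libraries, the real one included, too few for a share under 0.05. As many genes as in the real grouping were called in 10 of 10 splits for Rad21+/- against WT crypts (real 0, highest other 0), 10 for Apc Min against WT crypts (0, 13) and 10 for the 2 adenoma groups (0, 0). For Apc Min Rad21+/- against Apc Min crypts it was 1 (real 4908, highest other 2), as it was for Apc Min adenomas against Apc Min crypts (9075, 0) and WT crypts (8388, 0) and for Apc Min Rad21+/- adenomas against crypts (6717, 0). For gene lists the numbers of splits were 2 (real 15, highest other 16), 9 (6, 13) and 2 (15, 15) in the first 3 of these comparisons, and 3 (13, 15), 3 (18, 23), 3 (19, 20) and 9 (16, 20) in the other 4. List calls of similar number therefore arise in mixed groups, and the direction of a list call rests on few samples.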

How the results depend on the processing

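Limits first: the tests rest on 3 libraries per group, depth follows the Rad21 label, and sexes are mixed in WT crypts and Apc Min adenomas. Same-numbered libraries were not treated as pairs: correlations of their deviations ran from -0.268 to 0.25, with 0.145 and 0.187 in Apc Min Rad21+/- v Apc Min crypts. Peaks at changed genes were not analysed here, no filter could be dropped where adenoma values were recovered, and peak summits and false discovery rates were not used. For each result that moved, the cause was not tested.

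Genes past the threshold, by setting. DESeq2: 1697 in Rad21+/- v WT crypts, 62 in Apc Min v WT crypts, 38 between adenoma groups, 94 and 836 for the Apc and tissue interactions, and 1106 shared Rad21 effects. All groups in 1 fit: 1372 in Rad21+/- v WT crypts, 15 in Apc Min Rad21+/- v Apc Min crypts, 12 shared. Replicate block: 81 in Rad21+/- v WT crypts, 1 and 0 for the interactions. No filter: 8 in Apc Min v WT crypts. Total counts: 0 and 616 for the interactions. edgeR on recovered counts: 45 for the tissue interaction.

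With 1 library left out, genes ran from 0 to 1693 (Rad21+/- v WT crypts), 0 to 252 (Apc Min v WT crypts), 0 to 5 (adenoma groups), 1 to 121 and 1 to 1019 (interactions), 0 to 1132 (shared effects), 3455 to 4396 (Apc Min Rad21+/- v Apc Min crypts) and 5317 to 9817 (Apc Min Rad21+/- adenomas v crypts); lists ran from 4 to 13 (Apc Min v WT crypts) and 10 to 16 (adenoma groups).

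Lists past camera with an estimated correlation: 0 in 6 comparisons and 2 in Apc Min Rad21+/- adenomas v crypts. By fry: 0 in Rad21+/- v WT and Apc Min v WT crypts, 1 between adenoma groups. With a Y-linked term: 10 in Apc Min v WT crypts and 10 between adenoma groups.

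Signs that turned with total counts: Apc 0.0684 in Rad21+/- v WT crypts, 0.25 and 0.39 in Apc Min adenomas v Apc Min and WT crypts; Rad21 0.61 and 0.52 in the same 2, 0.088 in Apc Min Rad21+/- adenomas v crypts and -0.0643 for the Apc interaction; Ccnd2 0.16 and Wapl 0.0628 in Apc Min adenomas v crypts. With a Y-linked term in Apc Min v WT crypts: Rad21 0.0823, Axin2 0.23, Lgr5 1.13. With 1 library left out: Axin2 -0.23 to 0.0835 and Lgr5 -0.73 to 0.15 there; Apc -0.00507 to 0.236 and Rad21 -0.095 to 0.124 between adenoma groups; Apc -0.0212 to 0.217 in Apc Min Rad21+/- adenomas v crypts and -0.226 to 0.0251 for the Apc interaction.

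Crypt peaks overlapped: 4.01% (reciprocal 50%), 3.81% (score at least 100), 5.26% (equal numbers), 3.22% (score at least 40).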

Other observations

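The lists of clock and heat shock genes in this part were chosen after the main results were seen. Limits for their medians were fixed before the tests were run. No limits were fixed beforehand for intervals, directions of members, values per library or the test in Rad21+/- crypts. Clock output genes fell in Apc Min adenomas: all 8 of 8 genes that peak opposite to Bmal1 were lower than in Apc Min crypts, with a median log2 fold change of -2.30. The clock-controlled transcription factors Dbp (-4.28, limma adjusted p = 0.000363) and Hlf (-4.51, 0.000625) and the repressors Nr1d1 (-2.28, 1.01e-06) and Per2 (-2.95, 2.9e-05) were among them. Nfil3, which represses the targets of Dbp and peaks with Bmal1, rose by 1.93 (3.92e-05), but of the 5 genes that peak with Bmal1 (median -0.45) Cry1 (-0.97, 0.000633) and Clock (-0.48, 0.0058) fell and Bmal1 itself (Arntl) had 0.28 (0.523). In Apc Min Rad21+/- adenomas against crypts 2 of 9 genes that peak opposite to Bmal1, Dbp (-2.57, edgeR adjusted p = 0.0129) and Hlf (-3.08, 0.00117), were lower and Bhlhe41 was higher (3.25, 0.000789), with a median of -0.38. In Apc Min Rad21+/- against Apc Min crypts 4 of 8 genes that peak opposite to Bmal1 fell and none rose (median -0.59), namely Per2 (-1.17, edgeR adjusted p = 0.00745), Hlf (-1.04, 0.029), Per3 (-0.85, 0.0348) and Nr1d1 (-0.39, 0.00469), but so did Cry1 (-0.77, 0.00504) and Clock (-0.38, 0.00169), which peak with Bmal1, as does Nfil3, which rose (1.03, 0.00581).

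Beside Hspa1a and Hspa1b, 5 of 13 other heat shock factor targets fell and 3 rose in Apc Min Rad21+/- against Apc Min crypts. The chaperones Hsph1 (-1.13, edgeR adjusted p = 0.0023) and Dnajb1 (-0.69, 0.00043) were among the falls, and Hsp90ab1 (0.38, 0.0111) and Hspe1 (0.39, 0.0125) among the rises. On the joint scale Hspa1a was at 24.3 ± 14.6 CPM in Apc Min crypts, 7.41 ± 11.3 in WT, 1.13 ± 0.441 in Rad21+/- and 0.405 ± 0.121 in Apc Min Rad21+/- crypts, n = 3 each. A stress response during handling of the Apc Min crypts may explain this. The other 13 heat shock factor targets had a median of -0.138, which the limit fixed beforehand counted against that explanation. Their 95% bootstrap interval over genes was -0.535 to 0.073 and members went both ways, so that explanation was left undecided.

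Time of collection could also differ between the crypt groups. The median of genes peaking opposite to Bmal1 minus that of genes peaking with it was -0.39 in Apc Min Rad21+/- against Apc Min crypts. The limit fixed beforehand counted this against a different time, but the interval over genes was -1.7 to 0.209. That explanation was therefore left undecided too. In Rad21+/- against WT crypts the medians were -1.50 and 0.34, a difference of -1.84 (-3.67 to -0.813 over genes), and per library it was -2.92 to 0.214 against 0.8 to 1.2 in WT, relative to the mean of the 6 (exact p = 0.1, the lowest possible). No clock gene passed there, at edgeR adjusted p of 0.103 (Arntl, 1.67) or more, so a different time of collection remains possible for that pair. Times of collection, handling and batch per library would settle both.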
